A study of Saccharum hybrid cultivar with 68 samples.

How the data were processed

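The series measured RNA in leaf and stem of 2 sugarcane genotypes, ROC22 and GT86_887 (in the labels with a hyphen), which the series description says differ in sucrose content. Which genotype holds more sucrose is not given in the sources used here. Messenger RNA was sequenced in 36 libraries at the early, middle and late stages of sucrose accumulation, small RNA in 24 libraries at the early and late stages, and the degradome in 8 libraries. A degradome library sequences the 5' ends of uncapped RNA fragments, such as those left after a small RNA has directed the cleavage of its target. Each of the 12 mRNA groups and 8 small RNA groups had 3 libraries, taken from the titles and the genotype, tissue and growth phase labels. The labels do not state whether the libraries of a group came from separate plants, so the p-values measure only the spread between these libraries, which may be technical.

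Per the labels' protocols, total RNA was extracted with Trizol, molecules of 18-30 nt were selected on gels for the small RNA libraries, and fragments with a 5' monophosphate were captured for the degradome. The authors deposited a count of whole reads per assembled transcript (called a unigene below) and library, and per the file headers an FPKM value beside each count. For small RNA the authors deposited the count of tags per miRNA entry, with the entry's sequence, and per the file headers a TPM value, which was proportional to the count within a library and not scaled by length. Aligner, assembly, counting program, miRNA database, target caller and their versions are not given in the sources used here. The FPKM and TPM values deposited by the authors were compared with the counts and not tested. The total implied by TPM was 0.996 to 1.00 times the summed counts of a library.

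The mRNA table held 100182 unigenes, known by identifiers such as c141382.graph_c0. The files pair these with no gene name or annotation, and no reference genome was used here. For this reason 35 gene lists on sugar, wall, photosynthesis and transcription factor genes, fixed before the data were examined, could not be matched to unigenes and gave no result, and at most 2 unigenes that rose and 2 that fell are named per comparison. The small RNA table held 844 entries, 563 with a miR number and 281 predicted entries without one. Predicted entries are identified by sequence. The endings x, y and z of entry names were kept as deposited, and entries of a family may share reads. Some x and y entries of a family, such as those of miR166 and miR827, are nearly complementary in sequence. Targets are given for a family and were not checked for each entry. Of the 844 entries, 16 had a sequence identical to that of another entry, among them miR171-y and miR479-z.

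The degradome file gave 871 pairs of a miRNA and a target unigene with tag numbers per library, without category, p-value or cleavage site. A second set of 8 columns, headed as normalised tags, repeated these numbers and was not used. Titles and growth phase labels of 4 degradome libraries disagreed, with a late code in the title and the middle stage in the growth phase label, so no stage comparison was made within the degradome. With 1 library for each combination of genotype, tissue and title code, degradome tags have no replicate check.

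Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr at its default settings, 1 coefficient per group, a common and trended dispersion, the quasi-likelihood test and Benjamini-Hochberg adjustment. An adjusted p below 0.05 is called a pass, and verbs such as rose and fell are used only of items that passed. Stem and leaf were fitted apart, so that the groups of a tissue share their estimate of spread, and a fit of both tissues was used to compare them. Contrasts were ROC22 minus GT86_887 as the mean over stages, middle minus early and late minus middle for mRNA, late minus early for miRNA, stem minus leaf, and genotype by stage, which is late minus early in ROC22 minus the same difference in GT86_887. Levels are given in CPM (counts relative to the library total) scaled by TMM, as mean ± SD over libraries, and changes as log2 fold change ± SE. A TMM-scaled CPM can exceed an entry's plain share of a library.

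Items to be named were set before the data were examined. For mRNA these were the unigenes with the largest rise and fall among those that passed, lay above the median of mean levels and, except for genotype by stage, had groups whose libraries did not overlap. For miRNA these were the 5 entries with the smallest adjusted p in each direction, and the members of 32 conserved families, which were also put into 5 lists: families that target transcription factors, nutrient and copper families, auxin pathway families, small RNA machinery families and grass families. The lists overlap, with miR528 both among nutrient and copper families and among grass families. For the degradome these were the 15 pairs found in the most libraries, ranked by tags. Other pairs named with their fold changes were chosen after their values were seen.

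For pairs in which the miRNA and the target were both tested, the share with opposite signs of fold change was compared with 10000 random reassignments of targets among the miRNAs, in a two-sided permutation test adjusted over 7 contrasts. The mRNA fold changes in that test came from early and late libraries only. Many pairs share a miRNA or a target, and the test treats each pair as independent, so its p-values may be too small. Where a group held 0 counts of a named item, the fold is a bound from a floor of 3 counts over the group, and with 1 to 3 counts the ratio of counts per library total is given with its 95% counting interval. Intervals and floors cover counting error only.

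Summed counts ran from 17970015 to 24929466 per mRNA library and from 183654 to 1632186 per small RNA library, so a floor of 3 counts in a single library corresponds to 0.120 to 0.167 CPM for mRNA and to 1.84 to 16.3 CPM for small RNA. Every pair of libraries in a group differed by more than sampling noise, with a chi-square per tested item of at least 7.86 over 36 mRNA pairs and 34.4 over 24 small RNA pairs. The tests were tried on simulated counts with known changes, drawn from the means and library sizes of these data. For mRNA, with 100 changed unigenes per size, 62% of 2-fold and 85% of 4-fold changes were recovered for genotype in stem. For mRNA genotype by stage in leaf the shares were 15% and 50%. For miRNA, with 10 changed entries per size, the recovered shares of 2-fold and 4-fold changes were 0% and 50% for genotype in stem, 20% and 60% for late against early in stem, 0% and 10% for genotype by stage in stem, and 0% and 20% for genotype by stage in leaf. For genotype in stem fewer items changed in the simulation than passed in the data, so these shares need not hold for the real test. False calls made up 4.41% to 5.93% of mRNA calls and 0% to 11.1% of miRNA calls.

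Alternatives set before the data were examined were DESeq2 1.42.0 with its own size factors, no filter on low counts, the replicate number as a block, a fit of only the groups compared, leaving out libraries by replicate number and singly, and, for the target test, only pairs whose miRNA passed. For the genotype contrasts and all miRNA contrasts the fit of only the groups compared is the same fit. A limit to the strictest degradome category and a second correlation setting for gene lists were also planned and could not be run, since the files give no category and the lists were unusable. Leaving out 2 GT86_887 mRNA libraries together, and counting pairs with identical target and tags once, were chosen after the data were seen.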

Results

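Leaf and stem of the sugarcane genotypes ROC22 and GT86_887 (in the labels with a hyphen) were profiled by mRNA sequencing, small RNA sequencing and degradome sequencing across sucrose accumulation, the period in which the cane stores sugar in its stem. The series title asks whether microRNAs (miRNAs, short RNAs that guide the cleavage or repression of matching mRNAs) act on genes and transcription factors of sugar metabolism. The mRNA set held 36 libraries, with 3 for each genotype and tissue at the early, middle and late stages. The small RNA set held 24 libraries, with 3 for each genotype and tissue at the early and late stages. Counts per mRNA library summed to 17970015 to 24414986 in leaf and 19241718 to 24929466 in stem. Counts per small RNA library summed to 640674 to 1632186 in leaf and 183654 to 1374497 in stem. The entry miR166-y held 51.5% to 70.8% of the small RNA counts of a leaf library, and miR396-x held 32.5% to 72.9% of those of a stem library. In stem mRNA the most abundant unigene of a library held 2.28% to 17.8% of the counts, which was c121077.graph_c0 in every stem library but GT86_887 middle 2.

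Stem and leaf differed in most miRNA entries. The 3 members of miR166, a family that targets class III HD-ZIP transcription factors of leaf polarity and vascular patterning, lay lower in stem, with log2 changes of -5.82 ± 0.23 for miR166-y, -5.51 ± 0.25 for miR166-x and -5.07 ± 0.25 for miR166-z (SE, n = 12 libraries per tissue). Of these, miR166-x is nearly complementary in sequence to miR166-y, so it need not share the targets of miR166-y. Also lower in stem was miR160-x, of a family that targets auxin response factors (-5.39 ± 0.28, adjusted p = 5.29e-18). Higher in stem were miR319-y, of a family that targets TCP transcription factors (5.27 ± 0.27), at 21046 ± 11367 CPM in stem and 520.1 ± 207 CPM in leaf, and miR171-y, of a family that targets GRAS transcription factors (3.21 ± 0.26). The members of miR172, which targets AP2-like factors, rose toward stem by 3.12 ± 0.32, 2.18 ± 0.23 and 2.81 ± 0.32 for x, y and z. Those of miR156, which targets SPL factors of the juvenile to adult transition, were all lower in stem, miR156-x by -2.52 ± 0.19. Further entries with the smallest adjusted p were miR6218-x (4.84 ± 0.34), miR479-z (3.87 ± 0.28), which has the sequence of miR171-y, and the predicted entries AGCTGCCGACTCATTCACCCA (3.53 ± 0.28) and GCAACATGGGCAACACTTCTGGT (-7.33 ± 0.40).

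**Figure D1:**
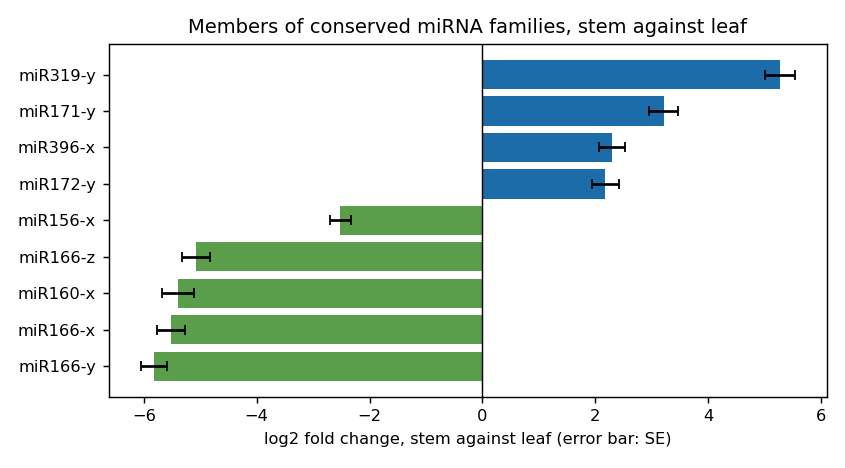
Log2 fold change of stem against leaf (horizontal axis) for 9 members of conserved miRNA families (vertical axis), bars starting at 0 with the SE of the edgeR fit over 24 libraries. The miR319, miR171, miR396 and miR172 members lie above 0 and the miR156, miR166 and miR160 members below it, from 5.27 for miR319-y to -5.82 for miR166-y.

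Of 285 tested entries 205 passed, 118 higher and 87 lower in stem, and the median over all tested entries was 0.61. Among families that target transcription factors, 18 of 37 tested members were higher in stem, 16 lower and 3 did not pass. Of 18 members of nutrient and copper families 3 were higher, all of them miR827, and 12 lower, among them miR528-x (-6.40 ± 0.35), a grass miRNA that targets copper proteins, and miR408-y (-4.91 ± 0.36). Of 9 auxin pathway members 1 was higher and 8 lower, among them miR393-x (-2.37 ± 0.23), which targets auxin receptors. Of 6 members of small RNA machinery families, which target DCL1 and AGO1, 4 were higher and 1 lower, and of 14 grass family members 4 were higher and 8 lower. Adjusted over the list alone, these lists held 34, 15, 9, 5 and 12 members that passed. No conserved family member that passed changed direction under any scaling or other alternative run for any miRNA comparison.

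Between the genotypes, stem miRNA profiles differed in the 3 miR171 members, which were higher in ROC22 by 2.70 ± 0.58, 1.74 ± 0.41 and 2.04 ± 0.44 on the log2 scale for x, y and z (n = 6 libraries per genotype). Both tested miR444 members, a grass family that targets MADS-box genes, were higher in ROC22 too, with 1.99 ± 0.37 for miR444-z. Lower in ROC22 were both members of miR399, which acts in phosphate supply through PHO2 (-1.52 ± 0.30 for miR399-y), the abundant miR396-x, of a family that targets growth-regulating factors (-1.04 ± 0.39), and miR168-x, which targets AGO1 (-1.41 ± 0.44). By the smallest adjusted p, miR530-z was higher in ROC22 at 31599 ± 10505 CPM against 4178 ± 3523 CPM (3.11 ± 0.42, adjusted p = 7.10e-06), as was miR5502-z (4.89 ± 0.71), and miR5381-z was lower (-4.69 ± 0.45). Predicted entries led both directions, with GATGTGTGATTCATGGACTGGCCC (5.66 ± 0.43), TCGAGTCGGTCGGTTCTCGCC (6.54 ± 0.59) and AGCACTCTGTGACTTTGGCTC (3.62 ± 0.47) higher in ROC22, and TCACTACCAGTTAAAGCCATGAAC (-6.55 ± 0.53), AGAAGGACTTTGTGCAGTGCATAT (-6.01 ± 0.59), CGCCGGCGCACGAGCTCGCCC (-6.06 ± 0.61) and ATGCACTGCACAAAGTCCTTCTTG (-5.61 ± 0.60) lower.

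In total 73 of 215 stem entries passed, 31 higher and 42 lower in ROC22. By list, 5 members were higher and 3 lower of 35 in families that target transcription factors, 0 and 4 of 14 in nutrient and copper families, 1 and 3 of 8 in auxin pathway families, 0 and 1 of 6 in small RNA machinery families and 4 and 0 of 10 in grass families. Adjusted over the list alone, 5, 2, 4, 1 and 4 members passed. The small RNA library ROC22 late stem 3 stood apart, with a mean correlation of 0.899 with the others of its group and 0.950 with the early ROC22 stem libraries. Without it 104 entries passed, 29 of them in conserved families against 19 with all libraries. Conserved family calls fell to 11 without GT86_887 early 1, 12 without ROC22 early 3 or without ROC22 late 2, and 5 without all libraries numbered 1, where 35 entries passed in all.

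In leaf, the genotypes differed in 75 of 180 miRNA entries as the mean over both stages. The grass miRNA miR528-x stood at 65198 ± 34762 CPM in ROC22 and 15957 ± 17546 CPM in GT86_887 (3.47 ± 0.31, adjusted p = 8.02e-08, n = 6 libraries per genotype), and miR528-y was also higher (2.63 ± 0.33). All 3 members of miR397, a family that targets laccases, all 3 of miR393, with miR393-x at 2.21 ± 0.27, and all 3 of miR156, with miR156-x at 1.17 ± 0.20, were higher in ROC22. By stage, miR397-y stood at 9472 ± 3621 CPM in ROC22 and 9497 ± 6713 CPM in GT86_887 early and 3203 ± 1171 and 253 ± 77.5 CPM late (n = 3 libraries each). For miR408-y, higher in ROC22 over both stages (1.92 ± 0.32), the early mean was lower there, 961 ± 360.2 against 1312 ± 326 CPM. Lower in ROC22 were miR1432-x (-5.55 ± 0.47), miR6223-x (-3.29 ± 0.39) and 2 of 3 members of miR395, which acts in sulfate uptake and assimilation (-2.01 ± 0.58 for miR395-z). Among predicted entries TTGAGTGCAGCGTTGATGAGC was higher (2.27 ± 0.28), and TTACCAACTGGGACTAAAGGT (-6.24 ± 0.60) and TTACCAACCGGGACTAAAGGT (-3.02 ± 0.36) were lower. The first of these differs from miR397-z only in its last base. AGCTGGTATGATCTGGCACCT had 116 counts in ROC22 and 0 in GT86_887, at least 33.4-fold higher, and AAGGGACATGGGATCTACCGTT had 106 counts in GT86_887 and 0 in ROC22, at least 40.9-fold lower, with a floor of 3 counts over the 6 libraries.

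Of these 75 entries 41 were higher and 34 lower in ROC22. By list, 9 members were higher and 6 lower of 32 in families that target transcription factors, 8 and 4 of 17 in nutrient and copper families, 5 and 1 of 9 in auxin pathway families, 1 and 0 of 6 in small RNA machinery families and 6 and 1 of 11 in grass families. Adjusted over the list alone, 15, 13, 6, 0 and 7 members passed. Whether genotype differences of a miRNA differ between stem and leaf was not tested.

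From the early to the late stage, 64 of 180 leaf miRNA entries passed, among them 15 of 17 members of nutrient and copper families. All 3 members of miR395 rose, miR395-z by 6.10 ± 0.49 to 270.2 ± 283 CPM from 2.08 ± 2.05 CPM and miR395-y by 3.61 ± 0.39 (n = 6 libraries per stage). All members of miR397, miR398, which targets copper/zinc superoxide dismutases, miR408, which targets blue copper proteins and laccases, and miR528 fell, with -3.64 ± 0.33 for miR397-x, -3.47 ± 0.36 for miR397-z, -3.35 ± 0.34 for miR408-y and -3.00 ± 0.31 for miR528-x. The predicted entry TTGAGTGCAGCGTTGATGAGC fell with them, from 43858 ± 21498 to 4867 ± 4825 CPM (-4.16 ± 0.30, adjusted p = 3.39e-09). Its sequence differs from miR397-z only in the last base and from miR397-x only in the base before. It may therefore not be independent of the miR397 family. All 3 miR393 members fell as well, while miR9774-z rose by 3.05 ± 0.28 to 83925 ± 37597 CPM, with the predicted entries CAGGGACCAGGAGATTGGATCT (3.04 ± 0.35) and ACTTGGATATGGAAGTCTTCTTTC (2.91 ± 0.38).

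Of the 64 entries 34 were higher and 30 lower at the late stage. By list, 5 members rose and 10 fell of 17 in nutrient and copper families, 3 and 2 of 32 in families that target transcription factors, 0 and 4 of 9 in auxin pathway families, 1 and 2 of 6 in small RNA machinery families and 0 and 5 of 11 in grass families. Adjusted over the list alone, 15, 5, 4, 3 and 5 members passed. No leaf library left out singly moved the count by over 1.5 times.

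In stem, 17 of 215 miRNA entries passed from early to late, and whether these changes differ from those of leaf was not tested. miR444-z rose by 1.63 ± 0.37 and miR827-x, of a family that targets SPX-domain genes of phosphate supply, by 2.03 ± 0.49, with miR894-z (1.77 ± 0.41), miR6234-y (1.73 ± 0.38) and miR6230-x (1.85 ± 0.47) (n = 6 libraries per stage, adjusted p = 0.0174 to 0.0213). The sequence of miR827-x is nearly complementary to that of miR827-y, which did not pass in this contrast (0.60 ± 0.35, adjusted p = 0.361). Whether miR827-x acts on the targets of the family was not tested. miR398-x fell by 2.33 on the log2 scale (SE 0.60) and miR530-x by 1.48 (SE 0.38), as did the predicted entries GAATGATGTCCGGTCCGAAGA (-1.80 ± 0.40), CCTCGCCGGCGCGCGAGCTCGCCCT (-1.69 ± 0.43) and CAACCAGCTGCTCAGGATCGAGGA (-3.25 ± 0.91). Of the 17 entries 8 were higher and 9 lower. By list, 1 member rose and 1 fell of 35 in families that target transcription factors, 1 and 2 of 14 in nutrient and copper families, 0 and 0 of 8 in auxin pathway families, 0 and 0 of 6 in small RNA machinery families and 1 and 0 of 10 in grass families, and adjusted over the list alone 2, 4, 0, 0 and 1 members passed. The count depended on single libraries: 46 entries passed without ROC22 late 3, which resembled the early libraries, 0 without ROC22 early 2 or without GT86_887 late 2, 9 without GT86_887 early 1 or ROC22 late 2, 10 without ROC22 late 1 and 11 without GT86_887 late 3. With the replicate number as a block 0 entries passed.

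The change from early to late differed between the genotypes for 11 leaf miRNA entries, 9 of them members of nutrient and copper families. In GT86_887 miR408-y went from 1312 ± 326 to 25.1 ± 8.35 CPM, and in ROC22 from 961 ± 360.2 to 487 ± 252 CPM (SD, n = 3 libraries each), an interaction of 4.73 ± 0.65 on the log2 scale (adjusted p = 0.000121). miR528-x went from 30932 ± 9841 to 982 ± 311 CPM in GT86_887 and from 87540 ± 27382 to 42857 ± 27818 CPM in ROC22 (3.95 ± 0.59), and miR398-y from 1020.3 ± 312 to 25.5 ± 16.5 CPM and from 684 ± 239 to 349 ± 112 CPM (4.34 ± 0.67). The others that passed included miR398-x (3.96 ± 0.65), miR397-y (3.66 ± 0.67), miR408-x (4.12 ± 0.75), miR397-x (2.42 ± 0.63) and miR528-y (2.47 ± 0.66). miR3627-z (2.40 ± 0.61), the predicted entry TTGAGTGCAGCGTTGATGAGC (3.19 ± 0.54) and miR408-z passed as well. In fits without 1 library, miR397-x and miR528-y never passed, and miR3627-z passed only without GT86_887 early 2. In the late GT86_887 leaf libraries miR397-x, miR398-x and miR528-y stood at 3.37 to 11.9 CPM. The floor of 3 counts there was 4.34 to 4.68 CPM, so the sizes of their interactions are uncertain. In all, 9 of 17 members of nutrient and copper families passed, all with a smaller fall in ROC22. All belong to miR397, miR398, miR408 and miR528, whose x and y entries are nearly complementary in sequence. The 9 may therefore not be independent of each other. The predicted entry is nearly identical in sequence to miR397-x and miR397-z and is not counted among these 9. miR408-z stood at 0, 0 and 1.37 CPM in the late GT86_887 leaf libraries. No counting interval was computed for it, so the size of its interaction is not given.

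**Figure D2:**
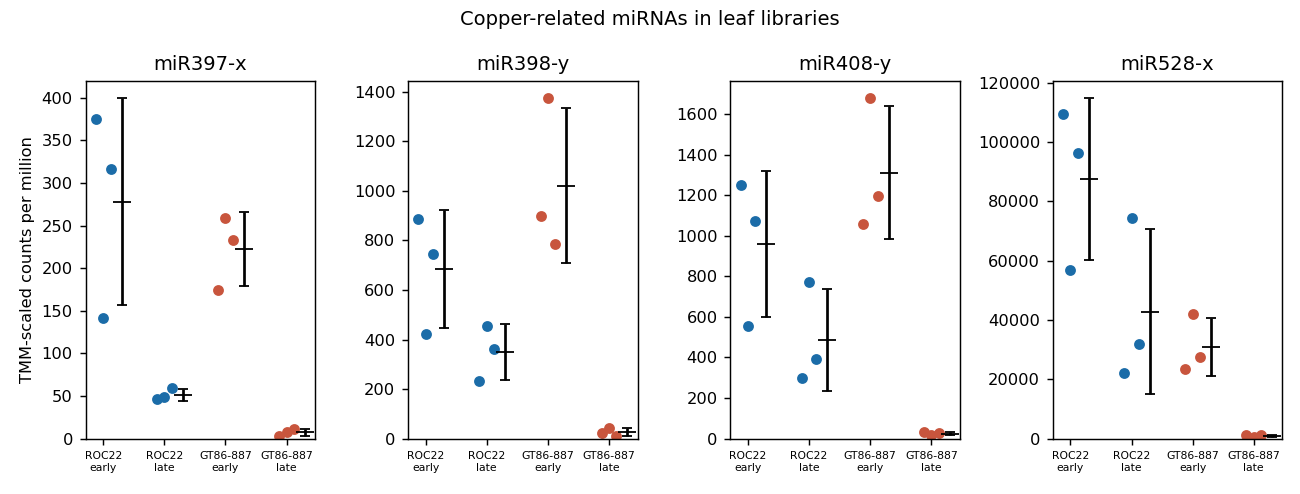
TMM-scaled CPM (vertical axes, each starting at 0) of miR397-x, miR398-y, miR408-y and miR528-x in leaf libraries of each genotype and stage, with points for the 3 libraries and a black line with bars for mean and SD. The late GT86_887 libraries lie near 0 in each panel, with a mean of 25.1 for miR408-y against 487 in late ROC22.

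These 11 of 180 entries were all higher in the contrast, and the median over all tested entries was 0.12. DESeq2, whose scaling moved that median to -0.10, passed 15 entries, 8 higher and 7 lower, and 8 of them were among the 11. By list, 9 members were higher and 0 lower of 17 in nutrient and copper families, 0 and 0 of 32 in families that target transcription factors, 0 and 0 of 9 in auxin pathway families, 0 and 0 of 6 in small RNA machinery families and 2 and 0 of 11 in grass families. The 2 grass family members are the miR528 entries, which are also among the 9. Adjusted over the list alone, 14 members of nutrient and copper families passed, 10 higher and 4 lower, with 0, 3, 0 and 3 in the other lists. Single libraries moved the count to 7 without ROC22 early 1, ROC22 early 2, ROC22 late 2, GT86_887 late 1 or GT86_887 late 2 and to 6 without GT86_887 late 3, and 0 passed without all libraries numbered 3, where the interactions were 4.59 ± 1.05 for miR408-y and 3.82 ± 0.84 for miR528-x. Of 100 splits of the libraries, the real one included, 12 gave as many. Splits that move unequal numbers of libraries between stages in the genotypes bring part of the stage difference into this contrast. Among 43 that moved equal numbers, a restriction chosen after the results were seen, the highest other count was 0. Those other splits mixed early and late libraries within their groups, which widens the spread, so that count of 0 cannot weigh chance.

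In stem, no miRNA entry passed the test of genotype by stage with edgeR, 0 of 215, with 35 entries at an unadjusted p under 0.05, and DESeq2 passed 0 with 41. Of simulated 4-fold interactions 10% were recovered there. In each of the lists 0 members passed, of 35, 14, 8, 6 and 10 tested, and adjusted over the list alone 1 member of nutrient and copper families did. The median over all tested entries was -0.28, and -0.40 with DESeq2. Without ROC22 late 3, whose profile lay closer to the early ROC22 stem libraries, 68 entries passed, and without ROC22 late 2 there was 1; without a filter on low counts 11 passed.

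In mRNA, the genotypes differed in more than 50% of the tested unigenes of each tissue. Since the files pair unigenes with no gene name, those named here stand by identifier. In stem c107402.graph_c2 was present in ROC22 at 22.8 ± 4.13 CPM with 2 counts in all GT86_887 libraries together against 4432, a ratio of 2306 (95% counting interval 638 to 19046, n = 9 libraries per genotype), and c87165.graph_c0 had a ratio of 2031 (562 to 16778). c111702.graph_c0 had 0 counts in ROC22 and 2124 in GT86_887, at least 680.4-fold lower, and c85991.graph_c1 was lower by a log2 change of -10.16 ± 0.34. In leaf c123657.graph_c0 had 3304 counts in ROC22 and 0 in GT86_887, at least 999.9-fold higher, and c137223.graph_c1 was higher by 10.69 ± 0.31. c115990.graph_c0 had 1 count in ROC22 and 10058 in GT86_887, a ratio of 11079 toward GT86_887 (1988 to 437630), and c54951.graph_c1 had 0 and 7495, at least 2752-fold lower.

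In stem 19926 of 36199 unigenes passed, 9641 higher and 10285 lower in ROC22, and in leaf 19398 of 37678, 9703 higher and 9695 lower. The GT86_887 middle libraries numbered 1 stood apart in both tissues. Of 173 leaf unigenes with a median above 2 CPM in ROC22 and below 0.05 CPM in GT86_887 this leaf library held 49.7% above 0.5 CPM, and of 277 with the opposite pattern 29.2%. The stem library held 48.2% of 168 and 31.3% of 278. All other GT86_887 libraries held at most 0.578% of the ROC22 markers and at least 98.9% of their own, and ROC22 libraries held at least 97.1% of theirs. These markers were chosen after the data were seen. Without these libraries 22396 unigenes passed in stem and 22377 in leaf.

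**Figure D3:**
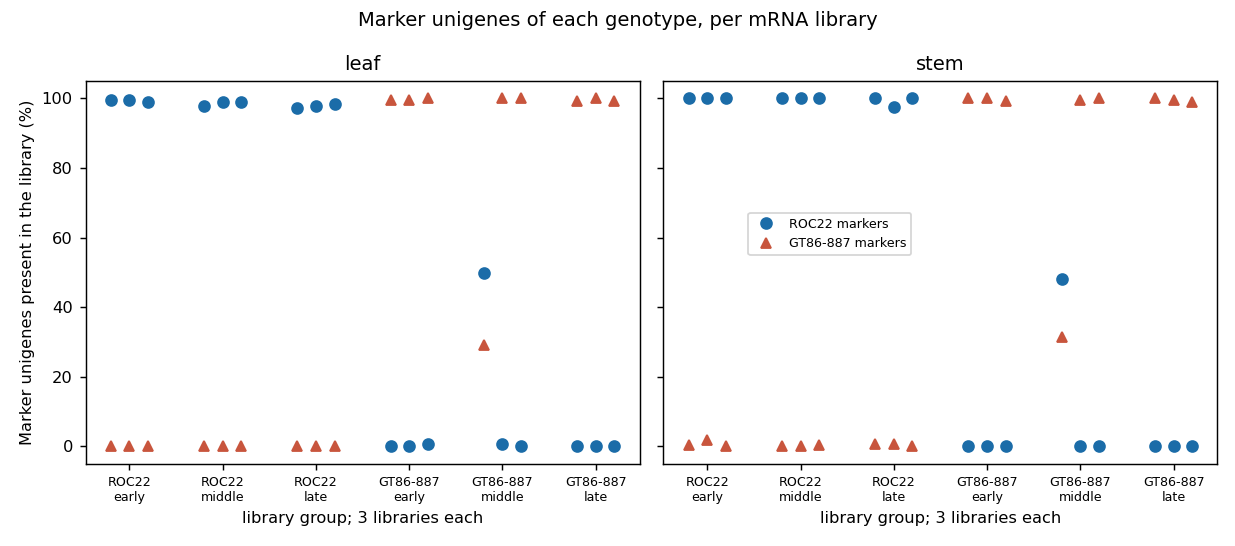
Percent of marker unigenes present above 0.5 CPM (vertical axis) in each mRNA library, by genotype and stage (horizontal axis), with circles for ROC22 markers and triangles for GT86_887 markers, in leaf (left) and stem (right). The GT86_887 middle libraries numbered 1 lie between the genotypes, at 49.7% and 29.2% in leaf and 48.2% and 31.3% in stem.

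Across stages, unigenes passed in both tissues at each step. From early to middle, c129806.graph_c0 (4.26 ± 0.47) and c129105.graph_c0 (3.93 ± 0.27) rose in stem, and c120627.graph_c0 fell from 104 ± 36.5 to 0.621 ± 0.544 CPM (-7.31 ± 0.65) and c134461.graph_c0 from 582 ± 189.7 to 5.08 ± 2.08 CPM (-6.81 ± 0.39) (n = 6 libraries per stage). In leaf c121288.graph_c0 (4.90 ± 0.26) and c129286.graph_c0 (4.65 ± 0.37) rose and c124626.graph_c0 (-7.54 ± 0.59) and c113508.graph_c0 (-6.74 ± 0.83) fell. From middle to late, c105576.graph_c0 (2.49 ± 0.30) and c120922.graph_c0 (2.34 ± 0.47) rose in stem and c135717.graph_c0 (-3.70 ± 0.42) and c115409.graph_c0 (-3.44 ± 0.42) fell, and in leaf c130735.graph_c0 (5.90 ± 0.74) and c108583.graph_c0 (5.54 ± 0.47) rose and c135768.graph_c0 (-3.85 ± 0.53) and c127667.graph_c1 (-3.35 ± 0.25) fell.

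From early to middle 8531 unigenes passed in stem, 4277 higher and 4254 lower, and 11376 in leaf, 5542 higher and 5834 lower. From middle to late 2387 passed in stem, 1335 higher and 1052 lower, and 7897 in leaf, 3962 higher and 3935 lower. Whether stage changes differ between the tissues was not tested. The late against middle count in stem was 4137 with DESeq2 and 827 in a fit of the groups compared. It fell to 1563 without ROC22 late 2, 1409 without GT86_887 late 1, 1077 without GT86_887 late 3, 1003 without ROC22 middle 2 and 998 without ROC22 middle 3, and was 3557 without the GT86_887 middle library numbered 1, which stood apart by its markers.

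The test of genotype by stage passed 50 unigenes in stem, 34 higher and 16 lower in the contrast, and 328 in leaf, 165 higher and 163 lower. In stem c134710.graph_c0 went from 18.6 ± 8.25 to 11.9 ± 3.05 CPM in GT86_887 and from 1.68 ± 0.592 to 26.0 ± 19.2 CPM in ROC22 (4.61 ± 0.71, adjusted p = 0.0406, n = 3 libraries each), and c135775.graph_c0 had an interaction of 3.26 ± 0.48. c123895.graph_c0 (-3.43 ± 0.62) and c132506.graph_c0 (-2.33 ± 0.41) went the other way. In leaf c132269.graph_c0 went from 2.91 ± 0.609 to 2.32 ± 0.556 CPM in GT86_887 and from 2.19 ± 0.987 to 38.1 ± 6.41 CPM in ROC22 (4.44 ± 0.53), c109229.graph_c0 had 4.40 ± 0.68, and c116174.graph_c0 (-8.12 ± 1.64) and c133721.graph_c0 (-5.57 ± 1.26) had the largest negative values named.

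Of 30 splits of the libraries, the real one included, 5 in stem and 7 in leaf gave as many. Splits that move unequal numbers of libraries between stages in the genotypes bring part of the stage difference into this contrast. Among 11 per tissue that moved equal numbers, a restriction chosen after the results were seen, the highest other count was 0. Those other splits mixed early and late libraries within their groups, which widens the spread, so that count of 0 cannot weigh chance. Single libraries moved both counts. In stem the count was 0 without ROC22 early 1, ROC22 late 2, ROC22 middle 3, GT86_887 early 2, GT86_887 early 3, GT86_887 late 1 or GT86_887 late 2, 1 without ROC22 early 3, ROC22 late 3 or GT86_887 early 1, 2 without ROC22 early 2 or ROC22 middle 1, 6 without ROC22 middle 2, 26 without GT86_887 late 3 and 325 without GT86_887 middle 1. DESeq2 gave 629, no filter 444, a fit of the groups compared 108 and the replicate number as a block 0. In leaf the count was 206, 184 and 103 without ROC22 early 1, 2 and 3, 144, 148 and 132 without GT86_887 early 1, 2 and 3, 106 and 138 without ROC22 late 2 and 3, 146 and 162 without GT86_887 late 1 and 3, 195, 200 and 207 without ROC22 middle 1, 2 and 3, and 1265 without GT86_887 middle 1, the leaf library with 49.7% of the ROC22 markers. DESeq2 gave 1228, no filter 1832 and a fit of the groups compared 849.

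Stem and leaf differed in 31165 of 42119 tested unigenes, 15067 higher and 16098 lower in stem. c109697.graph_c0 stood at 43.2 ± 12.7 CPM in stem and 0.0571 ± 0.134 CPM in leaf (10.74 ± 0.30, n = 18 libraries per tissue) and c135030.graph_c1 was higher in stem by 10.49 ± 0.37. c107799.graph_c0 (-11.48 ± 0.35) and c137369.graph_c0 (-11.20 ± 0.28) were lower, the latter at 0.0191 ± 0.0581 CPM in stem and 31.9 ± 16.9 CPM in leaf. No alternative moved this count by over 1.5 times.

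The degradome listed 871 pairs of 363 miRNA names and 752 unigenes, with 20630 tags in all. Tags per library numbered 2644 to 3033 in leaf and 2070 to 2990 in stem. The pair of miR1866-y and c141382.graph_c0 had the most tags, 4636, of which 15.3% came from leaf (95% interval 14.2% to 16.3%, Clopper-Pearson). This unigene was the most or second most abundant in all stem mRNA libraries but GT86_887 early 2 and 3, at 0.756% to 4.12% of counts. Whether its tags reflect cleavage or its abundance was not tested. The pair of miR172-y and c137236.graph_c0 had 1159 tags, 87.7% from leaf (85.7% to 89.6%), and miR172-y and c104350.graph_c0 had 263. The pair of miR160-x and c127776.graph_c1 had 358 tags, 85.8% from leaf (81.7% to 89.2%), where 246 of the 307 leaf tags came from the ROC22 early leaf library and the share without it was 54.5%, and both miR827-y and miR827-z were paired with c132560.graph_c0, with 135 tags, 47.4% from leaf (38.8% to 56.2%). The rule also named miR8736-z with c139900.graph_c1 (1035 tags), miR1039-y with c140119.graph_c0 (939 tags, 97.9% from leaf), miR2673-z and miR5662-z with c141382.graph_c0 (461 and 131 tags), miR3630-y with c140328.graph_c1 (365 tags), a predicted entry with c133455.graph_c0 (309 tags), miR8752-z with c122865.graph_c0 (200 tags), miR1524-z with c134130.graph_c0 (164 tags) and miR8584-z with c137238.graph_c0 (140 tags). Of the pairs 42 were listed in all 8 libraries and 354 in 1 library, and miR2673-z alone was paired with 88 unigenes.

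Between stem and leaf both members passed in 201 pairs, of which 115 had opposite signs. miR172-y was higher in stem (2.18 ± 0.23) and its targets c136849.graph_c0 (-2.59), c137236.graph_c0 (-1.83), c142330.graph_c0 (-1.51), c131530.graph_c0 (-1.22) and c104350.graph_c0 (-0.64) were lower, while c124637.graph_c0 (0.40), c129241.graph_c0 (0.36) and c134842.graph_c2 (0.99) were higher. miR166-y was lower (-5.82) and its target c138164.graph_c0 higher (2.59), and miR156-x was lower (-2.52) with c136846.graph_c0 (1.57), c118478.graph_c0 (1.20), c120659.graph_c0 (0.32) and c130401.graph_c3 (0.32) higher and c139690.graph_c0 (-3.62) and c139744.graph_c0 (-0.43) lower. miR164-x, of a family that targets NAC factors, was higher (1.68) and c131322.graph_c0 lower (-1.87). miR827-y was higher (2.94) and c132560.graph_c0, with 135 tags, lower (-0.93), as were miR396-x (2.29) and c121376.graph_c0 (-0.73) and miR169-z (2.27) and c139215.graph_c1 (-0.75). Moving the same way were miR159-x (-2.23) and c140872.graph_c1 (-2.98), miR162-y (1.96) and c142215.graph_c0 (0.91), miR444-y (0.54) and its targets c137993.graph_c0 (1.63) and c125122.graph_c0 (0.46), and miR827-y with c139337.graph_c0 (2.36). Between genotypes in stem both members passed in 33 pairs, of which 18 had opposite signs. There miR530-z was higher in ROC22 (3.11) and c136066.graph_c0, its target by 392 tags, lower (-1.42), while miR396-x (-1.04) and miR396-z (-1.12) moved the same way as c131841.graph_c0 (-0.43), miR171-y (1.74) as c119290.graph_c0 (0.79) and miR6223-x (-3.06) as c120643.graph_c0 (-0.36).

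Over all pairs with both members tested, 151 of 282 (53.5%) had opposite signs between stem and leaf against 49.7% in random reassignments (permutation p = 0.235, adjusted p = 0.412). For genotype the shares were 55.4% of 222 pairs in stem (adjusted p = 0.411) and 52.2% of 203 in leaf (adjusted p = 0.671), and for late against early 53.6% in stem (adjusted p = 0.411) and 52.2% in leaf (adjusted p = 0.891). For genotype by stage the share was 53.2% in stem (adjusted p = 0.671) and 60.6% in leaf, 123 of 203 pairs against 50% in random reassignments (permutation p = 0.00330, adjusted p = 0.0231). Pairs that share a miRNA or a target are not independent, and the reassignments treat them as such, so this p-value may be too small. Of the 11 leaf pairs whose miRNA itself passed genotype by stage, 54.5% had opposite signs, and of the 2 in which the target passed as well 0 did. Random reassignment cannot test the share of these 11 pairs. All their miRNAs changed in the same direction, so every reassignment gives the same share.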

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

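The counts of splits of the libraries were planned; the other tests in this part, and the restriction of the splits, were chosen after the results were seen. For an early library under a late label, the bound was also replaced after its value was seen, and by the earlier bound, the lowest mean correlation among the early libraries, the test argued against it. For depth in leaf the test was replaced as well, from the number of calls after thinning, which left it open, to their median change, and for scaling from the median of the entries that did not pass, which also argued against it.

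The change from early to late differed between the genotypes by a test of the difference for 11 miRNA entries of leaf, with 4.73 for miR408-y, 3.95 for miR528-x, 4.34 for miR398-y, 3.96 for miR398-x and 3.19 for the predicted entry TTGAGTGCAGCGTTGATGAGC. The last is nearly identical in sequence to miR397-x and miR397-z. The tables argue against scaling, since the median of the 11, 3.95, was 3.56 with DESeq2 size factors and 3.84 with library totals alone. They argue against a difference in depth. With all leaf libraries thinned to a total of 640674 the median of the 11 was 3.25 to 4.08 over 10 draws, with 7 to 11 passing. Each of 12 fits without 1 library kept 6 to 8 of the 11. That argues against a single library for miR528-x, miR408-y, miR398-y, miR408-x, miR398-x and the predicted entry, which passed in every such fit. miR397-x and miR528-y passed in no such fit, and miR3627-z only without GT86_887 early 2. Without all libraries numbered 3 edgeR passed 0, with interactions of 2.08 to 4.59 for the entries other than miR408-z. In that fit miR408-z was at 0 CPM in the remaining late GT86_887 leaf libraries. No counting bound was computed for miR408-z, so its size is not given. Chance was not excluded. Of 100 splits 12 gave as many as the real 11, with a highest other count of 43. Splits that move unequal numbers of libraries between stages in the genotypes bring part of the stage difference into this contrast, so they cannot weigh chance. Among 43 splits, the real one included, that moved equally many libraries in both genotypes the highest other count was 0. That restriction was chosen after the results were seen. Those other splits mixed early and late libraries within their groups, which widens the spread, so their count of 0 cannot weigh chance either. A difference between the genotypes in how these miRNAs change stays open as a biological explanation, untested beyond these counts.

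By marker unigenes the GT86_887 middle mRNA libraries numbered 1 of leaf and stem lay apart from GT86_887. The tables argue against an exchange of labels with a ROC22 library, since no ROC22 library held more than 1.80% of the GT86_887 markers. They argue against a mixture of RNA from both genotypes, since the median relative levels of both marker sets summed to at most 0.107. Material from a plant of another genotype may account for it, since both libraries had the same state for 173 of 183 markers shared by the tissues, 94.5% against 52.0% from the shares present in each. No biological explanation was tested.

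By a test of the difference, the change from early to late differed between the genotypes for 50 unigenes in stem, with 4.61 for c134710.graph_c0, 3.26 for c135775.graph_c0, -3.43 for c123895.graph_c0 and -2.33 for c132506.graph_c0. It differed for 328 in leaf, with 4.44 for c132269.graph_c0, 4.40 for c109229.graph_c0, -8.12 for c116174.graph_c0 and -5.57 for c133721.graph_c0. Chance was not excluded. Of 30 splits 5 in stem and 7 in leaf gave as many, with highest other counts of 2174 and 6642. Splits that moved unequal numbers of libraries in the genotypes brought part of the stage difference into this contrast, so they cannot weigh chance. Among 11 splits per tissue, the real one included, that moved equally many libraries in both genotypes the highest other count was 0. Those other splits mixed early and late libraries within their groups, which widens the spread, so their count of 0 cannot weigh chance either. They are also too few to exclude chance.

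The small RNA library ROC22 late stem 3 had a mean correlation of 0.950 with the early ROC22 stem libraries and 0.899 with its own group. The tables argue against an exchange of labels with an early library, since each of those correlated better with the other early ones, with a highest difference of -0.0689. They argue against lower depth, since late libraries 1 and 2, thinned to its total of 387659, kept a correlation of at least 0.964. An early library under a late label cannot be told apart, since 0.950 lies below the 0.961 to 0.967 of early libraries with each other but above the lowest value of 0.946 within other stem groups. No biological explanation was tested, and for genotype by stage in stem, where edgeR passed 0 entries with 35 at an unadjusted p under 0.05 and DESeq2 passed 0, the splits decide nothing about chance, since a real count of 0 is reached by 100 of 100 splits whatever the data, and the highest other gave 13.

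For the other counts only 1 of the splits, the real one, gave as many, which argues against a chance division of these libraries. The smallest share that 25 or 30 splits can give is 1 of 25 or 1 of 30. The splits cannot show whether the libraries of a group came from separate plants. The counts for mRNA late against middle and miRNA late against early in stem fell to 0 without some libraries. Over 30 splits the real and highest other counts were 19926 and 8692 for mRNA genotype in stem, 19398 and 5510 in leaf, 8531 and 548 for middle against early in stem, 11376 and 1154 in leaf, 2387 and 206 for late against middle in stem, and 7897 and 113 in leaf. Over 25 splits they were 31165 and 5741 for mRNA in stem against leaf. Over 100 splits of small RNA libraries they were 73 and 14 for genotype in stem, 75 and 25 in leaf, 17 and 9 for late against early in stem, 64 and 40 in leaf, and 205 and 100 for stem against leaf.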

How the results depend on the processing

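Leaving out both GT86_887 middle mRNA libraries numbered 1 from stem against leaf, and counting identical pairs once, were chosen after the data were seen; the other alternatives were planned. Of 91 named results, 1937 values under alternatives were computed, 1764 passed in the same direction, 173 no longer passed and 0 changed direction. Of the 173, 157 came from fits without some libraries, 101 concerned unigenes of genotype by stage and 62 miRNAs of late against early in stem. Causes were not tested, beyond the smaller number of libraries in fits without some of them.

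With DESeq2 the count moved by over 1.5 times to 4137 for mRNA late against middle in stem and to 629 and 1228 for mRNA genotype by stage in stem and leaf. Without a filter those last counts were 444 and 1832, and 11 for miRNA genotype by stage in stem. In a fit of the groups compared they were 108 and 849, and 827 for late against middle in stem. Of pairs whose miRNA passes, the opposite share for genotype by stage in leaf was 54.5%. Reassignment cannot test that share, since all those miRNAs changed in the same direction. Of distinct pairs the share was 61.5% (adjusted p = 0.0196), and these can still share a miRNA or a target. The other counts of all items stayed within 1.5 times under these settings. Calls in conserved families went from 6 to 10 for late against early in stem and from 9 to 14 for genotype by stage in leaf with DESeq2, and from 0 to 5 for genotype by stage in stem without a filter.

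Replicate numbers did not pair the libraries in mRNA stem or in miRNA, and in mRNA leaf a weak pairing was not excluded. Correlations of deviations between same-numbered libraries ran from -0.265 to 0.138 in mRNA stem and from -0.0907 to 0.212 in mRNA leaf. They ran from -0.434 to 0.172 in miRNA stem and from -0.317 to 0.222 in miRNA leaf. In this order 2 of 18, 10 of 18, 1 of 12 and 2 of 12 libraries correlated best with their own number. In mRNA leaf the mean was 0.027 for same numbers and -0.013 for other numbers. With the replicate block 0 items passed for mRNA genotype by stage in stem and 0 for miRNA late against early in stem, and the other counts of all items stayed within 1.5 times. Calls in conserved families went from 19 to 11 for genotype and from 6 to 0 for late against early in stem.

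Without some libraries counts ranged from 13640 to 22396 for mRNA genotype in stem, 3680 to 9633 for middle against early, 0 to 3557 for late against middle and 0 to 325 for genotype by stage. In leaf they were 13001 to 22377, 4477 to 12628, 2380 to 8748 and 0 to 1265, and 28198 to 31970 for stem against leaf, where single libraries were left out only for the GT86_887 middle libraries numbered 1 (32231 without both). For miRNA they were 35 to 104 for genotype in stem, 0 to 46 for late against early and 0 to 68 for genotype by stage, in leaf 30 to 91, 39 to 72 and 0 to 10, and 184 to 225 for stem against leaf. Calls in conserved families over all miRNA contrasts numbered 169, and 116 to 141 without a replicate number. They were 5 to 21 against 19 for genotype in stem, 10 to 26 against 37 in leaf and 17 to 23 against 30 for late against early in leaf. For late against early in stem they were 0 to 9 against 6. For genotype by stage they were 0 to 14 against 0 in stem and 0 to 7 against 9 in leaf. A limit to a strictest degradome category and a correlation setting for gene lists were not run. A floor of 3 counts in a single library corresponds to 1.84 to 16.3 CPM for small RNA; depth was thinned for genotype by stage in leaf miRNA, where 7 to 11 of the 11 calls passed, and for the small RNA libraries ROC22 late stem 1 and 2.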

Other observations

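The test of the hypothesis in this part was chosen after the results were seen, and its bound was replaced after its value was seen; by the earlier bound, a p of 0.05 or more, the test argued against the hypothesis.

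The miRNA miR530-z and its listed target c136066.graph_c0, a pair with 392 degradome tags, both passed with opposite signs in 4 contrasts. The log2 changes of miRNA and target were 3.11 and -1.42 for genotype in stem, 1.79 and -0.46 for genotype in leaf, -1.55 and 0.53 for late against early in leaf, and 0.60 and -4.68 for stem against leaf. In stem against leaf the miRNA change of 0.60 ± 0.25 lay at the median of all tested entries, 0.61. Its direction in that contrast may therefore depend on scaling. This pair was singled out after its values were seen.

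As a hypothesis, targets of conserved miRNA families listed in 4 or more degradome libraries may move against their miRNA more often than random pairs between stem and leaf. There 24 of 38 such pairs had opposite signs, 63.2% against 47.9% in random reassignments (permutation p = 0.0856, adjusted p = 0.30 over 7 contrasts). In the other 6 contrasts the adjusted p was 0.30 to 1, with shares of 40.5% against 51.2% for genotype by stage in stem, 52.9% against 55.6% for late against early in leaf, 51.4% against 48.8% and 52.9% against 51.6% for genotype in stem and leaf, 62.2% against 49.0% for late against early in stem and 64.7% against 48.8% for genotype by stage in leaf. The test did not pass, and with 38 pairs the hypothesis stays open.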
